A study of Arabidopsis thaliana with 9 samples.

How the data were processed

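The authors deposited FPKM (fragments per kilobase of gene, scaled to the fragments of the library) in 1 table of gene, condition, replicate and value, with the unit taken from the labels and no header. Per the labels' protocols, RNA from leaves was made into libraries with a stranded mRNA kit. The submitters' processing notes name TAIR10, Bowtie2 and bedtools without their roles. The program that made the FPKM, and whether it used strand, are not given in the sources used here. The table held 33302 features in each of 4 libraries, 2 per group, mapped to WT and K36M through the condition names quoted in the labels. Of these, 233 were several genes joined under 1 value, which leaves HTR3, PAO and CYP97C1 without a value of their own, and 7513 were listed at 0 in every library. Gene names and gene spans came from the RefSeq annotation of TAIR10.1, in which 32361 of 33069 single features were found, and no coordinates are given because the builds differ. A gene span was had for 17482 of the tested features.

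FPKM are not counts and the depth per library is not stated, so precision is given by replicate spread only. AT2G01021 took between 1.39% and 34.59% of a library's FPKM sum, and without it the sums still ranged from 756076 to 1406621. In 86.6% of 2664 genes under 1 FPKM in both replicate 2 libraries, the ratio of the values was a ratio of whole numbers up to 12 times a constant (within 0.0005 on the natural log scale), against 2.2% to 3.1% for the other pairs. Whole-number ratios arise where fragments are divided by a fixed length per gene. As the replicate 2 libraries shared them and the others did not, the replicate number was treated as a possible batch. Each batch holds 1 library per group, so its values are given without a test. No count model was run on the FPKM.

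Values were analysed as log2(FPKM + 1), a scale that understates changes of low genes, for the 17738 features with a mean of at least 1 FPKM. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. For 25 gene lists the members were fixed before the data were examined; 22 had at least 3 tested members and were compared with other genes by camera (inter-gene correlation preset to 0.01, adjusted over the lists). None of the 22 was called with an estimated correlation. With 2 libraries per group that estimate rests on few residuals and the test has little power, so a call lost there leaves a list undecided. A call with the preset correlation does not by itself tie a list to the genotype, since pairings that mix the genotypes also gave such calls. Members were also adjusted over the list alone, with no correction over the 22 lists. A member that passes only there is therefore not counted as called. Tables were handled with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

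The rule for named genes, also fixed before the data were examined, took HTR5 first. It then took up to 10 called rises and 10 called falls with K36M values beyond both WT values and a group mean of at least 5 FPKM. From each list it took up to 4 members, called members first and otherwise those with the greatest change. SDG8, FLC, MAF1 to MAF5, FT, SOC1, CRTISO, SVP, PR1 and PDF1.2A were taken whatever their values. ACD6, CHS, CYP79F1 and KNAT1, further list members, and AT2G01021 were chosen after their values were seen.

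Alternatives were other pseudocounts, filters and scalings, limma without the trend or with robust moderation, the replicate number as a block, each library left out in turn (a lone library is then assumed to vary like the other group), a 2-fold minimum, and camera with an estimated correlation or fry for the lists. A removal of each library's gene span trend by loess, protein-coding genes alone and library weights were added after seeing the data. The SDG8 list without CRTISO (mean -1.17) was also computed and is not used as a test, since its members' values were already known. The rule for the immune state test was tightened to need both genotypes after its value was seen. The limma step was tested on simulated data with the means of this comparison and variances drawn from its fitted mean-variance trend. In 10 simulations of 17738 genes, 200 genes were changed, all above a minimum mean expression. Simulated falls had no floor, so some went lower than log2(FPKM + 1) can show, and recovery of large falls may be overstated. The limma step recovered 1.8% of 4-fold, 61.2% of 16-fold, 92.2% of 64-fold and 97.4% of 256-fold changes, and 4.5% of its calls were false. That share depends on the number and size of the changes put in. False calls numbered 59 over the 10 simulations, and the real comparison called 7 genes, so the share cannot be applied to those calls. Means and variances per gene also do not describe a library that stands apart or genes that move together.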

Results

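RNA from leaves of 21-day-old Arabidopsis thaliana plants (Columbia-0 background) was sequenced in 4 libraries. Plants of both groups carried an inserted copy of the histone H3 gene HTR5 (AT4G40040), unmutated in the 2 libraries called WT here and with lysine 36 replaced by methionine in the 2 called K36M. The labels call the libraries of a group duplicate biological replicates. The comparison asks which transcripts differ between plants with the mutated and with the unmutated inserted histone. The values cannot tell an effect of the mutation from one of the insertion site or copy number of the inserted gene. H3K36me3 chromatin immunoprecipitation (ChIP) libraries from 5 genotypes are also listed in the series and were not analysed here.

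Expression was deposited as FPKM for 33302 features, of which 17738 had a mean of at least 1 FPKM and were tested. The FPKM of a library summed to 766727 and 2150314 in WT replicates 1 and 2 and to 932464 and 1353463 in K36M replicates 1 and 2. A 102-bp gene model beside ribosomal RNA genes, AT2G01021, held 1.39% and 34.59% of those sums in WT and 9.01% and 19.59% in K36M. WT replicate 1 stood apart from the rest, with Pearson r across genes of 0.834, 0.834 and 0.821 to the others, which correlated with each other at 0.937 to 0.95. Its long genes were higher and its short genes lower than in the other libraries, with a median log2 difference of -0.83 for 422 genes spanning under 600 bp and 0.72 for 1318 genes of 5000 bp or more.

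**Figure D1:**
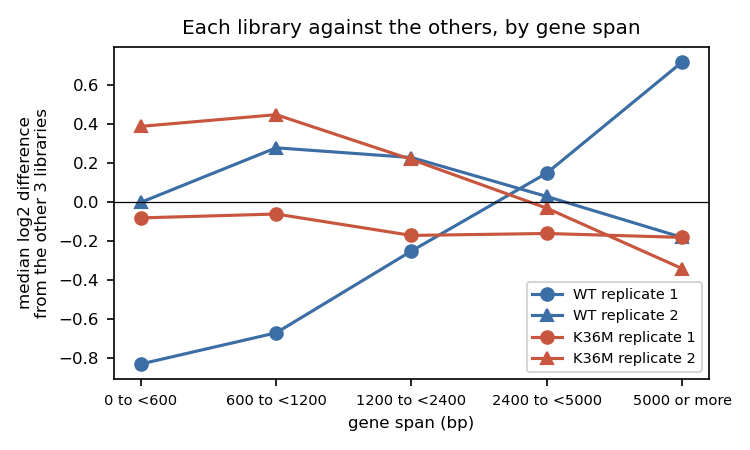
Median log2(FPKM + 1) difference of each library from the mean of the other 3, by gene span class in base pairs; circles are replicate 1, triangles replicate 2, blue WT and red K36M. WT replicate 1 runs from -0.83 in the shortest class to 0.72 in the longest.

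HTR5, the gene of the transgene, was read at 322 and 711 FPKM in the WT libraries and 391 and 582 FPKM in K36M, a log2 fold change of 0.00 ± 0.68 (SE; limma adjusted p = 1). Both groups carry the endogenous gene and an inserted copy, and FPKM per gene does not tell the mutated transcript from the unmutated one. Among 8 tested histone H3 genes, HTR9 had 42 and 91.4 FPKM in WT and 92.8 and 126 FPKM in K36M. The H3 gene list was not called by camera (mean log2 fold change 0.34, adjusted p = 0.11).

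In the test over all genes, 5 features were higher and 2 lower in K36M (limma, adjusted p from 0.026 to 0.029), and each of the 7 was listed at 0 in both libraries of one group. The small nucleolar RNA genes AT3G24612, AT1G03743 and AT1G20015 were listed at 0 in both WT libraries. They had 150 and 376, 72.3 and 183, and 63.2 and 112 FPKM in K36M. The gene AT1G35183 was at 0 in WT and at 45.3 and 65.9 FPKM in K36M, and the pseudogene AT3G42090 at 0 and at 32.4 and 36 FPKM. The leucine transfer RNA gene AT4G08345 was at 65.7 and 137 FPKM in WT and the 102-bp model AT1G74929 at 37.3 and 60.3 FPKM, both at 0 in K36M. A gene span under 600 bp was shared by 6 of the 7. All 271 plastid and mitochondrial features, which leaf cells use, were also listed at 0 in every library, so a 0 here is not a measure of absence. No call remained with the replicate number as a block or without either K36M library (limma, 794, 216 and 151 genes at an unadjusted p under 0.05), 13 genes were called without WT replicate 1, and 702 without WT replicate 2. The calls were also lost with no filter (limma, 25789 genes tested). The block left the fitted differences of the 7 as they were, with fewer residual degrees of freedom and adjusted p from 0.073 to 0.097. Without K36M replicate 1 or 2, which leaves 3 libraries, all 7 kept their direction, with adjusted p from 0.62 to 0.9 and from 0.87 to 0.98. With the block and the gene length trend removed together, an alternative added after seeing the data, 28 genes were called and all 7 were among them.

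CRTISO, the carotenoid isomerase whose expression is known to depend on the H3K36 methyltransferase SDG8, was at 20.4 ± 2.94 FPKM in WT and 0.412 ± 0.228 FPKM in K36M (SD, n = 2 each). Its log2 fold change was -3.93 ± 0.39 (SE), with a limma adjusted p of 0.083 over all genes and 4.1e-04 adjusted over the list alone. In the list of genes known to depend on SDG8, all 8 tested members had a log2 fold change below 0, from -3.93 for CRTISO to -0.06 for CYP79F1. Of these, 6 lay below both WT libraries in both K36M libraries. For a single gene the chance of this is 16.7% per direction. List members share the same libraries and are not independent, so this share is no test of a list, here or below. None of the 8 was called over all genes. When adjusted over the list alone, without correction over the lists, 4 passed as lower, CRTISO, MAF1, MAF4 and EXPA8. MAF1, a repressor of flowering related to FLC, had 26.5 ± 2.39 FPKM in WT and 5.52 ± 3.4 FPKM in K36M (SD, n = 2 each; limma adjusted p = 0.017 in this list). EXPA8, an expansin, had 14.1 ± 0.113 and 5.02 ± 1.9 FPKM (limma adjusted p = 0.033 in this list). As a set the list was lower in K36M than other genes (camera, mean log2 fold change -1.52, adjusted p = 1.5e-06). That call was lost with an estimated correlation (adjusted p = 0.5 with an estimated correlation). With the preset correlation, camera called 9 lists between the genotypes and 10 in each pairing of the libraries that mixes the genotypes. Such a call, here or below, thus does not by itself tie a list to the genotype. Between replicate 1 libraries the mean was -1.40 and between replicate 2 libraries -1.64. SDG8 itself was read at 6.18 and 2.25 FPKM in WT and at 2.45 and 1.94 FPKM in K36M, a log2 fold change of -0.60 ± 0.51 (limma adjusted p = 1). The 17 tested genes of the histone methylation machinery were not called as a set (camera, mean -0.24, adjusted p = 0.31).

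**Figure D2:**
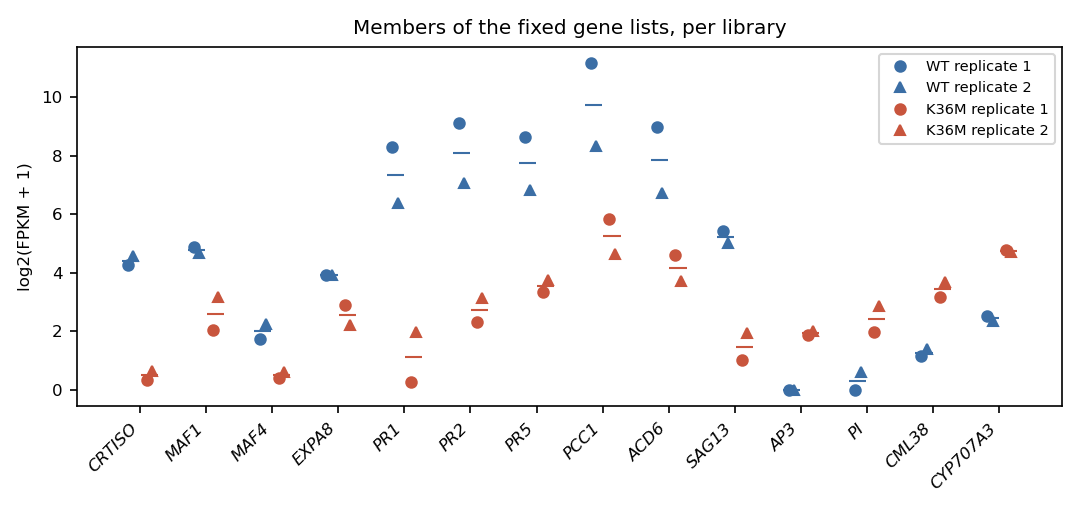
Expression as log2(FPKM + 1) of 14 list members in each library; blue is WT, red K36M, circles replicate 1, triangles replicate 2, short lines the mean of each group. CRTISO lies at 18.3 and 22.5 FPKM in WT and at 0.251 and 0.573 FPKM in K36M, and PR1 at 314 and 82.4 FPKM against 0.195 and 2.88 FPKM.

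Genes of salicylic acid immunity were lower in K36M as a set, with a mean log2 fold change of -2.47 over 23 tested members (camera, adjusted p = 2.5e-17), a call lost with an estimated correlation (adjusted p = 0.57 with an estimated correlation). All 23 had a log2 fold change below 0, and in 18 both K36M values lay below both WT values. The chance is 16.7% per direction for a single gene, and the members are not independent. None was called over all genes, and 5 passed as lower only when adjusted over the list alone, PR1, PR2, PR5, ACD6 and PCC1. PR1, a secreted pathogenesis-related protein, had 198 ± 164 FPKM in WT and 1.54 ± 1.9 FPKM in K36M (SD, n = 2 each; limma adjusted p = 0.31 over all genes and 0.0044 adjusted over the list alone). PR2, a glucanase, had 346 ± 304 and 5.88 ± 2.66 FPKM, and PR5 had 258 ± 205 and 10.7 ± 2.36 FPKM. PCC1 stood at 2290 and 320 FPKM in WT and 56.8 and 23.8 FPKM in K36M. The 2 WT libraries differed by a mean of 2.54 log2 units over this list, WT replicate 1 being the higher, and the 2 K36M libraries by -0.10 (replicate 1 minus replicate 2). The mean was -3.79 between replicate 1 libraries, -1.15 between replicate 2 libraries, -1.20 without WT replicate 1 and -3.74 without WT replicate 2.

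Floral organ identity and KNOX genes were higher in the K36M libraries, with a mean log2 fold change of 1.54 over 8 tested members (camera, adjusted p = 3.8e-09, and adjusted p = 0.5 with an estimated correlation). All 8 had a log2 fold change above 0 and 7 lay above both WT libraries (chance 16.7% for a single gene). None was called over all genes. AP3 and PI, MADS-box genes of petals and stamens, passed as higher only when adjusted over the list alone (limma adjusted p = 0.026 each). AP3 was listed at 0 in both WT libraries and at 2.69 and 3.02 FPKM in K36M, and PI was at 0 and 0.527 FPKM and at 2.91 and 6.28 FPKM. SEP3 had 0.616 ± 0.244 FPKM in WT and 3.93 ± 2.48 FPKM in K36M (SD, n = 2 each). The meristem gene STM was at 0 and 9.73 FPKM in WT and 10.6 and 7.89 FPKM in K36M. The list's mean depended on the pseudocount and filter, at 2.98 with a pseudocount of 0.1 and 1.11 with no filter. The mean was 1.88 between replicate 1 libraries and 1.19 between replicate 2 libraries. It was 1.07 without WT replicate 1 and 2.00 without WT replicate 2. Over this list WT replicate 1 lay -0.93 log2 units from WT replicate 2, and the K36M libraries differed by -0.24 (replicate 1 minus replicate 2). Part of the list's rise thus rests on WT replicate 1, the library that stands apart. Bulk RNA does not tell a change within cells from a different share of tissues in the samples, for this list or for the cell division list.

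Flowering promoters were higher as a set (camera, mean log2 fold change 0.72 over 12 members, adjusted p = 1.1e-04; adjusted p = 0.5 with an estimated correlation), and flowering repressors lower (mean -0.60 over 13 members, adjusted p = 0.0082; adjusted p = 0.66 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone. MAF1, MAF4 and MAF5 are also members of the SDG8 list, so the repressor and SDG8 results are not independent. Their log2 fold changes were -2.18, -1.5 and -1.44, against a median of -0.39 over the repressors. MAF1 and MAF4 had limma adjusted p of 0.056 and 0.11 over the repressors alone, and 0.017 and 0.033 over the SDG8 list alone. Among the promoters, 5 of 12 lay above both WT libraries (chance 16.7% for a single gene). They included FUL with 3.04 ± 0.475 and 8.83 ± 4.75 FPKM and AP1 with 0 and 0.573 FPKM in WT and 2.03 and 2.34 FPKM in K36M. FT, the mobile flowering signal, had 1.89 and 0.361 FPKM in WT and 2.89 and 4.56 FPKM in K36M, and SOC1 had 28.4 and 9.15 FPKM and 19.4 and 23 FPKM. Among the repressors, 5 of 13 lay below both WT libraries (chance 16.7% for a single gene). MAF4 had 3.05 ± 1.02 and 0.417 ± 0.153 FPKM. MAF5 had 0.16 and 6.64 FPKM in WT and 0.0596 and 0.14 FPKM in K36M. MAF2 had 23 and 7.26 FPKM in WT and 4.57 and 8.04 FPKM in K36M, MAF3 7.46 and 6.84 FPKM and 4.03 and 6.7 FPKM, and SVP 48.8 and 58.3 FPKM and 49.6 and 41.1 FPKM. FLC was below the filter at 0.0894 and 2.6 FPKM in WT and 0.305 and 1.01 FPKM in K36M and was not tested. Means for replicate 1 and replicate 2 libraries were 0.77 and 0.68 for the promoters and -0.24 and -0.95 for the repressors. The repressors' mean was -1.0 without WT replicate 1, and their call was lost without WT replicate 2 (mean -0.19, camera adjusted p = 0.75).

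Cell division genes were higher in K36M, with a mean log2 fold change of 0.78 and all 18 tested members above 0 (camera, adjusted p = 3.0e-08; adjusted p = 0.57 with an estimated correlation). In 10 of the 18 both K36M values exceeded both WT values (chance 16.7% for a single gene). None passed over all genes or adjusted over the list alone. KNOLLE, the syntaxin of the dividing cell's plate, had 8.8 ± 2.36 FPKM in WT and 25.4 ± 14 FPKM in K36M, and CYCB1;3 had 1.24 and 1.95 FPKM and 3.7 and 4.39 FPKM. The touch and wounding list was also higher (camera, mean 0.76 over 12 members, adjusted p = 3.1e-04; adjusted p = 0.5 with an estimated correlation). None of its members was called over all genes. CML38, a calmodulin-like protein, and CYP707A3, an abscisic acid hydroxylase, passed as higher only when adjusted over the list alone (limma adjusted p = 0.01 and 0.0096). CYP707A3 had 4.41 ± 0.488 and 25.6 ± 0.992 FPKM and CML38 1.41 ± 0.295 and 9.97 ± 2.73 FPKM (SD, n = 2 each). The means between replicate 1 and replicate 2 libraries were 1.13 and 0.43 for cell division and 0.78 and 0.74 for touch and wounding. The cell division mean was 0.39 without WT replicate 1 and 1.18 without WT replicate 2, called in both cases. WT replicate 1 lay below WT replicate 2 over this list by a mean of -0.79 log2 units and the K36M libraries differed by -0.08 (replicate 1 minus replicate 2). WT replicate 1 was also the lowest library for the meristem genes STM and KNAT1 and the epidermal gene PDF1. STM stood at 0 FPKM there and at 9.73, 10.6 and 7.89 FPKM in the others, KNAT1 at 0.0354 against 2.69, 4.19 and 3.67 FPKM, and PDF1 at 4.81 against 404, 313 and 213 FPKM. Over the epidermis list it lay -1.62 log2 units from WT replicate 2.

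Heat shock genes were lower as a set (camera, mean -0.76 over 8 members, adjusted p = 0.0045; adjusted p = 0.57 with an estimated correlation), and none passed over all genes or adjusted over the list alone. HSP70-4 had 19.5 ± 2.63 FPKM in WT and 5.73 ± 2.03 FPKM in K36M, and HSP90.1 36.9 and 3.72 FPKM and 3.45 and 4.33 FPKM. Anthocyanin and flavonoid genes were higher (camera, mean 0.96 over 12 members, adjusted p = 5.6e-04; adjusted p = 0.81 with an estimated correlation), with no member passing either adjustment. DFR had 5.29 and 36.9 FPKM in WT and 42 and 75.5 FPKM in K36M, and CHS, the entry enzyme of the pathway, had a log2 fold change of 0.04 ± 0.85 (limma adjusted p = 1). Both calls ended without WT replicate 1, where the means were -0.39 for heat shock (adjusted p = 0.25) and -0.31, in the opposite direction, for anthocyanins (adjusted p = 0.4), and the anthocyanin mean was 2.22 without WT replicate 2. Within replicate 1 and replicate 2 the means were -1.17 and -0.36 for heat shock and 1.97 and -0.06 for anthocyanins.

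**Figure D3:**
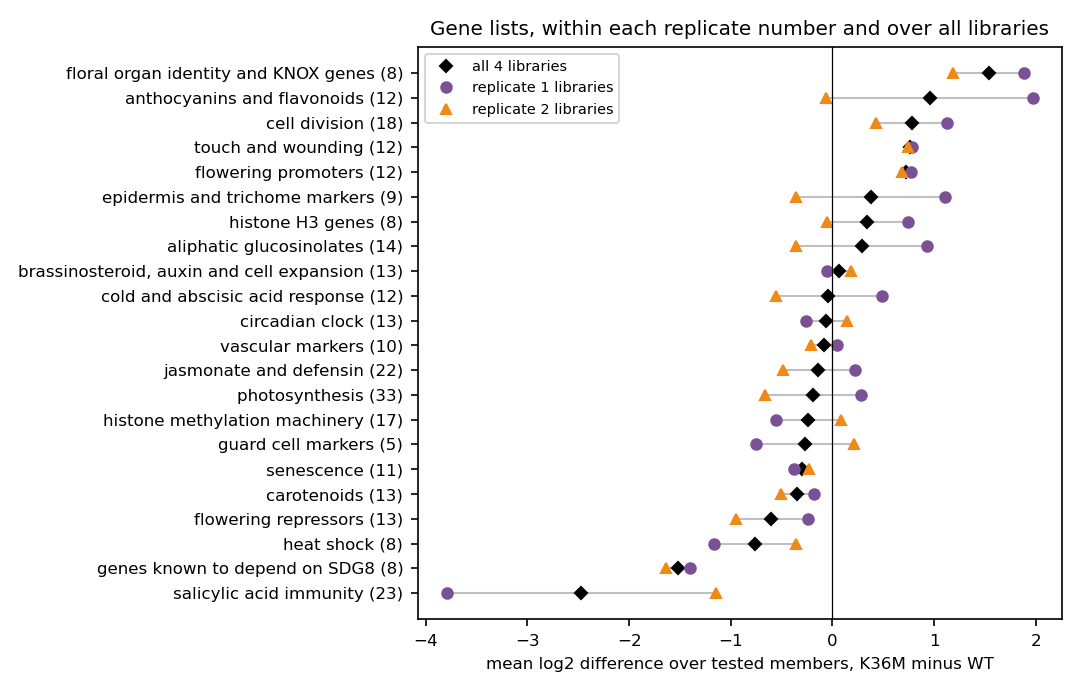
Mean log2 difference, K36M minus WT, over the tested members of each list (number in brackets), between the replicate 1 libraries (circles), between the replicate 2 libraries (triangles) and over all 4 (diamonds). Salicylic acid immunity lies at -3.79, -1.15 and -2.47, and anthocyanins at 1.97, -0.06 and 0.96.

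The remaining tested lists were not called. Photosynthesis genes had a mean log2 fold change of -0.19 over 33 members (camera, adjusted p = 0.69), called lower without WT replicate 1 (-0.81, adjusted p = 3.6e-04) and higher without WT replicate 2 (0.42, adjusted p = 0.025). With the gene length trend removed, an alternative added after seeing the data, they were called lower (-0.30, adjusted p = 0.02), and with a replicate block as well they were not (-0.30, adjusted p = 0.069). RCA, rubisco activase, stood at 7440 and 14500 FPKM in WT and 6750 and 7080 FPKM in K36M. Values of single members of the multigene RBCS and LHCB1 families may be uncertain, as near-identical copies can share reads, which was not examined. In the senescence list (camera, mean -0.30, adjusted p = 0.38) SAG13, an alcohol dehydrogenase-like gene, passed as lower only when adjusted over the list alone. SAG13 had 36.5 ± 7.81 and 1.89 ± 1.27 FPKM (limma adjusted p = 0.24 over all genes and 0.0021 in the list). In the carotenoid list (mean -0.35, adjusted p = 0.4) CRTISO alone passed (limma adjusted p = 6.7e-04 in the list). Jasmonate and defensin genes went both ways, with TAT3 at 244 and 10.1 FPKM in WT and 0.546 and 0.715 FPKM in K36M, VSP1 at 4.6 and 8.77 FPKM and 25.2 and 30.3 FPKM, and PDF1.2A at 2.63 and 32.6 FPKM and 1.08 and 2.93 FPKM. The jasmonate list's mean was -0.14 and its median -0.19 although camera ranked it upward (adjusted p = 0.77). The circadian list also differed in sign, with a mean of -0.06, a median of 0.07 and an upward camera direction (adjusted p = 0.7). Aliphatic glucosinolate genes had a mean of 0.29 (adjusted p = 0.084; called at 0.27, adjusted p = 0.032, without K36M replicate 2), cold and abscisic acid genes -0.04 (adjusted p = 0.8; -0.73, adjusted p = 0.021, without WT replicate 1 and 0.66, adjusted p = 0.088, without WT replicate 2), and brassinosteroid, auxin and expansion genes 0.06 (adjusted p = 0.53). Guard cell markers had a mean of -0.27 (adjusted p = 0.49), vascular markers -0.08 (adjusted p = 0.77), and epidermis and trichome markers 0.38 (adjusted p = 0.44). The epidermal gene PDF1 was at 4.81 and 404 FPKM in WT and 313 and 213 FPKM in K36M. No root, seed storage or pollen marker was tested, with highest values of 1.32, 0.308 and 0.355 FPKM in any library. Without WT replicate 2 the histone H3 (0.83), glucosinolate (0.95) and epidermis (1.19) lists were called higher and the histone methylation (-0.54) and guard cell (-0.83) lists lower. Without WT replicate 1 the means of the same 5 lists had the opposite sign and none was called, at -0.14, -0.38, -0.43, 0.05 and 0.29 in that order.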

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

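The gene length removal, protein-coding and library weight alternatives were chosen after seeing the data. The count of 7 genes held with either pseudocount, both rescalings, limma without trend or with robust moderation and a 2-fold minimum, and was 6 at a mean of at least 5 FPKM. It was 0 with no filter (limma, 25789 genes tested, 1175 at an unadjusted p under 0.05) and 0 with the replicate number as a block (794 at an unadjusted p under 0.05). The filter alters no gene's values, so the fitted differences of the 7 were the same with no filter. Deviations of same-numbered libraries correlated at 0.128 across genes, which with 2 pairs does not establish a pairing. The count was 5 with the gene length trend removed (3 higher), 28 with that removal and a replicate block (8 higher, 20 lower, all 7 among them), 2 among protein-coding genes and 12 with library weights. Leaving out 1 library gave from 0 to 702 calls, with 13 without WT replicate 1 (2 of the 7 among them) and 702 without WT replicate 2. The 9 called lists became 0 with an estimated correlation and 0 with fry, and between 9 and 14 when a library was left out; with the gene length trend removed they were 10, photosynthesis being added (mean -0.30, adjusted p = 0.02), and 9 with a replicate block as well (photosynthesis adjusted p = 0.069). By fry's test for change in either direction, the SDG8 and carotenoid lists passed (adjusted p = 0.035 each). Both lists hold CRTISO, so these are not independent results. Every other tested carotenoid gene had an unadjusted limma p of 0.39 or more. The photosynthesis mean ran from -0.81 to 0.42 over the left-out libraries, called in opposite directions without WT replicate 1 and without WT replicate 2, and the anthocyanin mean from -0.31 to 2.22. CRTISO was called without WT replicate 2 (limma adjusted p = 0.021), with library weights (0.043) and with length removal and block (0.017), and had adjusted p from 0.017 to 1 over all alternatives. Without a call on either side, 5 of 1208 values of named genes and 9 of 220 list means changed sign under other settings, as did 26 of 380 and 12 of 88 with a library left out. Many of the other settings cannot change a sign, so their low shares do not measure robustness. The filters, variance moderation, replicate block, protein-coding genes alone and library weights leave a gene's fitted difference as it was. The block, protein-coding genes alone, library weights, estimated correlation and fry leave the list means as they were. The cause of the changes between settings was not tested, beyond the greater number of genes tested without a filter and the fewer libraries when one is left out. A count model was not run, since FPKM are not counts. Depth is not stated, and 4-fold changes were mostly missed in the simulated data.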

Other observations

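The gap counts, the gene length tests, the differences within a genotype and the other pairings of the libraries were chosen after the result was seen, and the genes named next were chosen after their values were seen. Over all tested genes, 50 had K36M values separated from both WT values by a gap of at least 4-fold on the log2(FPKM + 1) scale, 33 lower and 17 higher, against 23 when the 4 libraries were paired by replicate number and 13 in the crossed pairing. At a gap of at least 2-fold the genotype grouping did not stand out, with 279 genes against 284 by replicate number and 78 crossed. Groups did not overlap in 31.4% of genes against 38.7% and 29.3% (chance 33.3%), and 730 genes had an unadjusted p under 0.05 against 1136 and 372. In 14 of the 50 one group was listed at 0, most of these among the 17 higher. The 33 lower include PR1, PR2, PR5, PCC1 and ACD6 of the salicylic acid list, each higher in WT replicate 1 than in WT replicate 2. Genes that move together are not independent, so the excess over the other pairings is not a count of separate changes. Lower in both K36M libraries were PCR1, a plant cadmium resistance gene (1080 and 92.9 FPKM in WT, 1.85 and 1.63 FPKM in K36M), and LURP1, a gene needed for defence against downy mildew (902 and 211 against 4.6 and 13.8 FPKM). The glutathione transferase GSTF2 had 1300 and 440 FPKM in WT and 61.9 and 58.1 FPKM in K36M. The calcium/proton exchanger CAX3 had 16.2 and 15.5 against 2.79 and 2.5 FPKM. AT5G42530, an abundant transcript, had 4180 and 4960 FPKM in WT and 431 and 640 FPKM in K36M, and AT2G25510 had 3850 and 2770 against 479 and 689 FPKM. Higher was AT1G22470, at 0.199 and 1.06 FPKM in WT and 11.2 and 15.8 FPKM in K36M. None of these passed the limma test over all genes.

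WT replicate 1 stood apart from the other 3 libraries, along a first principal component holding 62.2% of the variance. A trend with gene span as the whole reason is argued against. With each library's span trend removed, log2 differences from WT replicate 1 still had a mean SD of 1.092, against at most 0.754 among the other pairs. Gene span is not transcript length, and a trend with transcript length was not examined. Values did differ in form by replicate number, with 773 and 882 values shared with another gene in the replicate 2 libraries of WT and K36M and 162 and 152 in the replicate 1 libraries. As the reason that WT replicate 1 stands apart, values made differently for the replicate 1 libraries are argued against, since K36M replicate 1 lay no farther than an SD of 0.761 from the replicate 2 libraries. A difference in the plants, the RNA or the library of that sample stays open, and no biological explanation was tested because the design gives none within a group.

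Salicylic acid immunity genes were lower in K36M by the preset correlation (camera, adjusted p = 0.57 with an estimated correlation). The gene span trend as the whole reason is argued against, the list's mean being -2.41 with that trend removed. Transcript length was not examined. Whether WT replicate 1 makes the whole difference stays open: without it the mean was -1.20, which rests on a single WT library and is smaller than the difference between the WT libraries. An immune state that varies between plants of one genotype stays open as a candidate explanation, as the WT libraries differed by 2.54 log2 units over the list but the K36M libraries only by -0.10. The WT difference alone was as large as that between the genotypes. The rule needed both genotypes, a condition added after the value was seen. The 2.54 rests on WT replicate 1, the library that stands apart, and the list's mean was -1.22 for replicate 2 against replicate 1 libraries and -1.32 in the crossed pairing, against -2.47 between the genotypes. The genotype stays open too, as an effect that 2 libraries per group did not separate from that variation.

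The 7 called features may reflect models whose value drops to 0 whatever the grouping. In the real grouping 13 tested genes were at 0 in both libraries of one group and above 5 FPKM in both of the other. Pairing the libraries by replicate number also gave 13, and the crossed pairing gave 9. Those pairings called 12 and 7 genes and 10 lists each, against 7 genes and 9 lists in the real one. With the replicate number as a block the real grouping called 0 genes and 9 lists. With 3 groupings in all, no share under 0.05 can be reached.

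A hypothesis on gene length was set against the values. If long genes were lower in K36M in particular, the median log2 difference of genes of at least 5000 bp should lie 0.2 or more below that of genes under 600 bp, both against the mean of the WT libraries and against WT replicate 2 alone. It lay -0.77 from it against the mean of both (medians of -0.39 and 0.37), which carries the length trend of WT replicate 1. Against WT replicate 2 alone it lay -0.05 from it, short of the size sought, but a single WT library does not exclude the dependence.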
